A study of Solanum lycopersicum with 6 samples.

How the data were processed

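Polyadenylated RNA of tomato leaves was sequenced on an Illumina NextSeq 500 with single-end reads of 75 bp from TruSeq RNA libraries, per the labels' protocols. Plants grew in a glasshouse with 16 h of light and 8 h of dark at 23 °C, and about 100 mg of tissue and 10 µg of RNA were used per sample. The labels name the tissue as expanded leaf, while the extraction text speaks of whole plant tissue. The 3 groups (WT, TET3, NTS) have 2 libraries each, and groups and replicate numbers were taken from the sample titles.

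The authors deposited, for each library, a table of whole-number read counts per gene and a table of counts per gene and per repeat. Reads were trimmed with fastp 0.23.2 and aligned with STAR 2.7.9a, per the submitters' processing notes. The counting program, its settings, the genome build and the annotation are not given in the sources used here. The gene tables held 34901 features, namely 34688 tomato gene models, 211 organelle genes and 2 transgene features (TET3c and NeoR/KanR). The gene rows of the repeat tables held between 3.02% and 4.02% more counts than the gene tables, and between 112 and 130 genes per library had 0 counts in the gene table and 100 or more in the repeat table. Reads with several possible positions thus appear to have been counted in the repeat tables and not in the gene tables. Genes with near-identical copies are uncertain for this reason.

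The repeat tables held 51869 rows named by element, a middle field and a class. In 99.1% of rows the middle field was a number that splits one element over several rows, so rows were summed per element into 675 families. That choice was made after the form of the tables was seen and before any group was compared, and the rows as deposited were kept as an alternative. Family and class names are those of the tables. Without coordinates of repeats and genes, reads of a repeat inside a host gene could not be separated from reads of the repeat itself.

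The deposited counts were tested in R 4.3.3 with edgeR 4.0.16. Genes passed the default low-count filter (a minimum count of 10 and a minimum total of 15), libraries were scaled by TMM, and dispersions were estimated robustly over all 6 libraries with a term per group. Each comparison used the two-sided quasi-likelihood F-test with Benjamini-Hochberg adjustment, and a feature was called at an adjusted p under 0.05. Repeat families were scaled by the effective library sizes of the gene tables, because TMM on repeats alone would remove a change common to all of them. The biological coefficient of variation was 14.2% for genes and 11.2% for repeat families. CPM values use the effective library size, except that transgene CPM values use the unscaled gene table total. A count of 0 was set against a floor of 3 counts, and 95% intervals of single counts are exact and cover counting error only. No library pair agreed within sampling noise (chi-square per degree of freedom of 19.2 in WT, 46.0 in TET3 and 11.9 in NTS).

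The steps were tested on simulated counts of all 6 libraries, in 10 draws each. Means were pooled over the 6 libraries, their library sizes were kept, and changes were put into the TET3 group only. NTS was left unchanged there, unlike in the data, so these rates may differ from those of the real comparisons. Over 19752 features with 200 changed, 58.7% of genes changed 2-fold and 88.3% of genes changed 4-fold were recovered, and on average 11.9% of the calls were false, above the nominal level. Over 619 repeat families with 60 changed, 85.7% and 98.3% were recovered and 6.08% of calls were false. Counts of changed genes should be read with that excess of false calls in mind.

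Gene lists were tested with camera of limma 3.58.1 (correlation preset to 0.01, and again estimated), with fry of limma beside it. For fry the test for a common direction is given unless stated. Lists with under 5 tested genes got counts only. The lists for DNA methyltransferases and DDM1, DNA demethylases, RNA-directed DNA methylation, CETS flowering regulators, fruit ripening, floral and meristem identity, circadian clock and the tocopherol epiallele were fixed before the data were examined. Those for photosystem and Rubisco small subunit, pathogenesis-related proteins, wound and jasmonate, phenylpropanoid and flavonoid, heat shock, RNA silencing and glandular trichome genes were added once the identifiers were known and before any value was seen. Lists planned by gene description could not be filled, since no descriptions were given. The reference table (assembly SLM_r2.1) matched 0 of the identifiers directly, so the files pair no identifiers with names. Of 141 listed identifiers the name intended for 86 was found in that table on the same chromosome and within 0.03 of its relative gene order, and only these genes are named. A further 34 had no entry by that name and 5 had it elsewhere on the chromosome, and these stayed in the lists without a name. Another 5 were left out because the name lay on another chromosome, and 11 because the tables lacked the identifier. The check by gene order cannot tell neighbouring copies apart. The identifiers intended as HSP17.7 and HSP17.8 both met the entry HSP17.8, so names within such clusters are uncertain.

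Genes named in the text follow a rule fixed before the data were examined. It takes the 10 largest rises and falls per comparison among called genes with at least 1 CPM in the higher group and no overlap between groups, up to 4 called members per list, all tested methyltransferase, demethylase and CETS genes, the 5 largest rises and falls among repeat families, and the 10 largest changes shared by TET3 and NTS. As applied, only the 2 largest rises and 2 largest falls per comparison were taken among genes, whether or not their name was checked. Of shared changes, up to 2 genes and 5 families were taken per direction. Counts of named calls kept or lost (30 genes in NTS vs WT, 34 genes in TET3 vs NTS, 101 in all) leave out TD in these 2 comparisons.

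Calls shared by TET3 vs WT and NTS vs WT were set against independent lists and against 60 simulations of unchanged groups sharing the WT libraries. Shares of repeat counts were compared by exact permutation. Classes of repeats were compared by Fisher's exact test over the tested families, adjusted over 4 classes and 3 comparisons, a test chosen after the repeat results had been seen. Alternatives covered DESeq2 1.42.0, RLE size factors, no low-count filter, a replicate block, each comparison fitted on its own groups, each library left out, a minimum log2 change of 1, TMM on repeats alone and the repeat share without the 10 largest families. The gene rows of the repeat tables, the repeat rows as deposited and repeat counts per gene count were chosen after seeing the data. Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for tables and plots.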

Results

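Messenger RNA was sequenced from expanded leaves of tomato (Solanum lycopersicum) in 3 groups of 2 libraries. WT was the wild type. TET3 carried hTET3cd, the catalytic domain of human TET3, an enzyme that oxidises 5-methylcytosine and so starts the removal of DNA methylation. NTS was a sibling of the transgenic plants that had not inherited the transgene. The gene tables held 22211684 and 24066440 counts in WT, 31543678 and 26641953 in TET3, and 21488205 and 27512536 in NTS. Of 34688 tomato gene models and 211 organelle genes, 19750 had enough counts to be tested. Counts on repeats were summed into 675 families, of which 619 were tested. The labels give the same line, A T1, for all 6 libraries, WT included. They do not say whether libraries came from separate plants, and the series names a single non-transgenic sibling, so p-values measure only the spread between these libraries.

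The transgene was read first, as a check of the labels. TET3c, the transgene's own feature, took 313999 and 268975 counts in the TET3 libraries, or 9954 and 10096 CPM (counts scaled to library size). The WT libraries held 0 and 4 such counts, where a count of 0 allows up to 0.135 CPM. The NTS libraries held 295 and 54, or 13.7 CPM (exact 95% interval 12.2 to 15.4) and 1.96 CPM (1.47 to 2.56). The selection marker NeoR/KanR followed the same order, with 4427 and 4888 counts in TET3, 5 and 0 in NTS, and 0 in both WT libraries. The labels were therefore kept as deposited, and both features were left out of all counts of genes below.

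The NTS libraries stood furthest from the others. The first principal component held 64.8% of the variance and placed NTS at 73.0 and 63.2, WT at -25.4 and -3.40, and TET3 at -55.9 and -51.5. The second held 15.9% and parted WT, at -36.9 and -33.2, from TET3 and NTS, at 9.43 to 24.5. The 10 most abundant genes took 5.26% and 4.72% of counts in NTS, and 3.57% to 3.71% in the other libraries.

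Against the wild type, 199 genes were called in the transgenic plants by edgeR. TD (Solyc09g008670.3), a threonine deaminase whose leaf form acts in defence against herbivores, fell from 47.6 ± 20.3 CPM in WT to 3.04 ± 1.14 in TET3 (SD, n = 2). Its log2 fold change was -3.99 (SE 0.46, edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 0.0323). CHI17 (Solyc02g082930.3), a chitinase of the pathogenesis-related proteins, fell from 39.4 ± 0.744 to 16.1 ± 2.09 CPM, a log2 fold change of -1.29 (SE 0.11, edgeR adjusted p = 0.0169). Of genes without a checked name, Solyc01g058705.1 had no count in either WT library and 6.25 ± 0.395 CPM in TET3, at least 100-fold higher against a floor of 3 counts over the WT group. Solyc05g012240.3 likewise had no WT count and 5.21 ± 0.470 CPM in TET3, at least 83.4-fold higher. Solyc01g044370.3 fell from 5.09 ± 0.396 to 0.368 ± 0.131 CPM. In all, 67 genes rose and 132 fell at an adjusted p under 0.05, of 19750 tested, and 3914 had an unadjusted p under 0.05.

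Among light-harvesting genes none passed edgeR over all genes between TET3 and WT. CAB1B, CAB3C and CAB4, which encode chlorophyll a/b-binding proteins of the photosystems, had log2 fold changes of -2.82, -1.28 and -1.18 with edgeR adjusted p of 0.0880, 0.0703 and 0.0726. Adjusted over the list alone, 3 of the 7 tested members of the photosystem and Rubisco small subunit list fell, and DESeq2 called 3 and an unadjusted p under 0.05 was reached by 3. Camera placed this list below other genes (adjusted p = 0.00443), and likewise the wound and jasmonate list (adjusted p = 0.0120) and the pathogenesis-related list (adjusted p = 0.0193). These 3 calls were lost with an estimated correlation (camera adjusted p = 0.658 each), and fry for a common direction called none of the 3 lists (adjusted p = 0.306 each). Without regard to direction fry gave an adjusted p = 0.0246 for each of them, and the same for the circadian clock list, which had no called gene. Within the wound list TD was the called member of 13 tested, and 2 fell adjusted over the list alone. Within the pathogenesis-related list CHI17 was the called member of 8, and 1 fell adjusted over the list alone.

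None of the genes that write and erase DNA methylation in tomato itself was called by edgeR over all genes between TET3 and WT. CMT3, a chromomethylase of non-CG sites, stood at 0.888 and 1.11 CPM in the TET3 libraries and at 1.35 and 1.47 in the WT libraries, with a log2 fold change of -0.51 (SE 0.25, edgeR adjusted p = 0.322). CMT2 had a log2 fold change of -0.46 (SE 0.10, edgeR adjusted p = 0.103). DML2, a DNA glycosylase that removes methylated cytosine, had 0.06 (SE 0.08). None of the 10 tested methyltransferase and DDM1 genes, 4 demethylase genes or 3 CETS flowering regulators was called by edgeR or by DESeq2, and 1, 0 and 0 of them had an unadjusted p under 0.05. Adjusted over the list alone, 1 methyltransferase gene fell. The other lists without a call were RNA-directed DNA methylation, fruit ripening, floral and meristem identity, circadian clock, tocopherol epiallele, phenylpropanoid, heat shock, RNA silencing and glandular trichome. Together the 13 lists without an edgeR call held 79 tested members, of which 14 had an unadjusted p under 0.05 and 4 were called by DESeq2. Adjusted over the list alone, 1 tocopherol gene rose and 1 trichome gene fell among these other lists. Median and mean log2 change differed in sign for the trichome list (0.51 and -1.04), for the CETS list (-0.13 and 0.02), for the demethylase list (0.00 and -0.01) and for the methyltransferase list (0.01 and -0.12). For the RNA silencing list both were negative (-0.01 each) while camera ranked it upward (adjusted p = 0.945).

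The number of changed genes in TET3 rested on the libraries used. It was 0 without WT replicate 1 and 0 without WT replicate 2, where 3439 and 2623 genes had an unadjusted p under 0.05. The number also fell without either NTS library, although these enter neither group mean and act only through the shared spread, the low-count filter and the scaling. Without either TET3 library it rose. DESeq2 called 1081 genes. Of the 6 gene calls named for TET3 vs WT, 0 were kept without either WT library. TD lost its call without each of the 6 libraries in turn (edgeR adjusted p of 0.0717 and 0.0884 without WT replicate 1 and 2, 0.0859 and 0.0568 without TET3 replicate 1 and 2, and 0.104 and 0.103 without NTS replicate 1 and 2). CHI17 lost its call without WT replicate 1 (0.0612), WT replicate 2 (0.0972), NTS replicate 1 (0.0817) and NTS replicate 2 (0.0812). Solyc01g058705.1, Solyc05g012240.3 and Solyc01g044370.3 lost theirs without each WT and each NTS library (edgeR adjusted p from 0.0518 to 0.157).

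Many repeat families rose in TET3. The family rnd-6_family-2701, a Gypsy element of the long terminal repeat (LTR) retrotransposons, which copy themselves through RNA, rose from 0.469 ± 0.325 CPM in WT to 4.97 ± 0.842 in TET3. Its log2 fold change was 3.42 (SE 0.35, edgeR adjusted p = 0.00162), and 4.34 and 2.81 without WT replicate 1 and 2. The families rnd-6_family-359 and rnd-5_family-1961 rose by log2 fold changes of 2.20 (SE 0.19) and 2.12 (SE 0.20). The DNA transposon family rnd-5_family-2250 went the other way, from 23.7 ± 3.87 to 1.64 ± 0.335 CPM, a log2 fold change of -3.86 (SE 0.19, edgeR adjusted p = 3.99e-05). Of 619 families 115 rose and 6 fell, and the median log2 fold change over all families was 0.29.

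Members of the LTR class made up most of these rises. In TET3, 84 of 266 LTR families rose against 31 of 353 others (Fisher's exact test, odds ratio 4.78, adjusted p = 8.25e-12). Gypsy gave 57 of 165 and Copia 26 of 94. DNA transposons gave 13 of 162, fewer than the remaining families (odds ratio 0.304, Fisher's exact adjusted p = 0.000125), and LINE elements 3 of 30. The summed level of LTR families was 5806 ± 488 CPM in WT and 7668 ± 593 in TET3, and that of DNA transposons 3815 ± 93.4 and 4377 ± 273 (SD, n = 2). Families are not independent of each other. Camera ranked LTR families above other families, but the call was lost (adjusted p = 0.909 with an estimated correlation).

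Repeat families together took 1.44% ± 0.0615 of counts in WT, 1.71% ± 0.0368 in TET3 and 1.29% ± 0.0481 in NTS (SD, n = 2). Both TET3 libraries, at 1.69% and 1.74%, lay above both WT libraries, at 1.49% and 1.40%. The 95% Wilson intervals of these shares reached at most 0.00491 percentage points to either side, for counting error only. The exact permutation test of 2 against 2 libraries gave a two-sided p of 0.333, the smallest that the 6 assignments allow. Scaling on repeat counts alone sets the common shift near 0, moving the median log2 fold change from 0.29 to -0.01, and left 27 families that rose and 11 that fell in TET3. Of these 27, 26 were LTR families. Without WT replicate 2 the calls in TET3 dropped to 12, and all 10 families that still rose were LTR families, while without WT replicate 1 there were 82 calls. The other counts were 105 without TET3 replicate 1, 55 without TET3 replicate 2, 65 without NTS replicate 1 and 60 without NTS replicate 2.

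**Figure D1:**
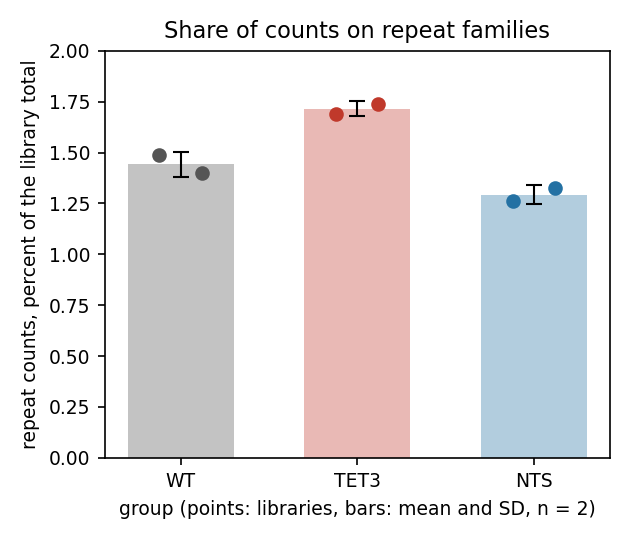
Share of counts on repeat families in percent of each library's total (y axis) for WT, TET3 and NTS (x axis). Points are libraries, bars the mean and error bars the SD (n = 2). The TET3 libraries, at 1.69% and 1.74%, lie above the WT and NTS libraries.

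The NTS libraries differed from WT in genes of photosynthesis and defence. CAB1B (Solyc02g070950.1) rose from 3.03 ± 0.466 CPM in WT to 304 ± 139 in NTS, a log2 fold change of 6.65 (SE 0.40, edgeR adjusted p = 0.00435). All 7 tested members of the photosystem and Rubisco small subunit list rose, over all genes and adjusted over the list alone. Among them were CAB3C at 2.88 (SE 0.22), CAB4 at 2.67 (SE 0.21) and RBCS1, a small subunit of the carbon-fixing enzyme Rubisco, at 1.99 (SE 0.23). These families have near-identical copies that can share reads. In the gene rows of the repeat tables, where reads with several positions appear to have been counted, CAB1B had a log2 fold change of 6.61. RBCS1 lost its call without WT replicate 1 (edgeR adjusted p of 0.0559) and NTS replicate 1 (0.0793). Camera gave the list an adjusted p = 1.66e-22, and an adjusted p = 0.223 with an estimated correlation, while fry gave an adjusted p = 0.0270.

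Defence genes moved in both directions in NTS. Of 8 tested pathogenesis-related genes 3 rose and 1 fell, and 4 rose and 1 fell adjusted over the list alone. CHI9, a basic chitinase, rose from 50.9 ± 11.5 to 540 ± 108 CPM (log2 fold change 3.41, SE 0.23, edgeR adjusted p = 0.00435). PR1a1 rose by 2.69 (SE 0.48) and the osmotin-like NP24 by 2.15 (SE 0.15), while CHI17 fell, with -1.74 (SE 0.11). Of 13 wound and jasmonate genes 4 rose, over all genes and adjusted over the list alone. The proteinase inhibitor gene PIIF rose from 3.77 ± 1.93 to 130 ± 56.6 CPM (log2 fold change 5.10, SE 0.46, edgeR adjusted p = 0.00667), TD rose by 1.65 (SE 0.39) and AOS2, of jasmonate synthesis, by 0.42 (SE 0.07). Camera called the pathogenesis-related list (adjusted p = 0.00449, and adjusted p = 0.415 with an estimated correlation) but not the wound list (adjusted p = 0.187), which it called with the replicate block (adjusted p = 0.0104) and without NTS replicate 1 (adjusted p = 0.0339). TD lost this call without each of the 6 libraries in turn, with an edgeR adjusted p of 0.0858 and 0.134 without WT replicate 1 and 2, 0.0608 and 0.0556 without TET3 replicate 1 and 2, and 0.129 and 0.191 without NTS replicate 1 and 2. CHI17 and NP24 lost theirs without NTS replicate 1 (0.0506 and 0.0530), AOS2 without WT replicate 1 and 2 (0.112 and 0.0607) and NTS replicate 1 and 2 (0.127 and 0.126), and PR1a1 without WT replicate 1 (0.0677) and NTS replicate 1 and 2 (0.125 and 0.109). Without WT replicate 2 the log2 fold change was 3.52 for PR1a1 and 5.76 for PIIF.

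Several flavonoid genes fell in NTS. Of 10 tested phenylpropanoid and flavonoid genes 4 fell, and 5 adjusted over the list alone. They included chalcone synthase CHS2, from 248 ± 60.7 to 40.9 ± 26.1 CPM (log2 fold change -2.60, SE 0.54, edgeR adjusted p = 0.0340), F3H at -2.01 (SE 0.38) and the flavonol regulator MYB12 at -1.64 (SE 0.18). Camera gave the list an adjusted p = 0.000136, and an adjusted p = 0.415 with an estimated correlation, while fry gave an adjusted p = 0.0791. CHS2 lost its call without WT replicate 1 (edgeR adjusted p of 0.146), WT replicate 2 (0.0741), NTS replicate 1 (0.0871) and NTS replicate 2 (0.114). F3H lost its call in the same order at 0.131, 0.0554, 0.0793 and 0.0955, and MYB12 without NTS replicate 1 and 2 (0.0819 and 0.0626). Without NTS replicate 1 the log2 fold change was -3.46 for CHS2 and -2.60 for F3H.

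Some genes of DNA methylation rose in NTS, among them 2 chromomethylases and 2 demethylases. CMT3 went from 1.41 ± 0.0831 to 5.30 ± 0.697 CPM (log2 fold change 1.90, SE 0.23, edgeR adjusted p = 0.00896) and CMT2 from 30.5 ± 2.84 to 42.1 ± 1.79 CPM (0.46, SE 0.10). A pair of genes listed for the chromatin remodeller DDM1, whose names the reference table lacked, rose as well, so that 4 of 10 tested genes of this list rose, and 5 rose and 1 fell adjusted over the list alone. Of 4 demethylase genes DML1 (0.48, SE 0.09) and DML2 (0.35, SE 0.08) rose, also adjusted over the list alone. Camera did not call the methyltransferase list (adjusted p = 0.0988), and the demethylase list was too small for it. CMT2 lost its call without WT replicate 1 (edgeR adjusted p of 0.157), WT replicate 2 (0.0519), NTS replicate 1 (0.205) and NTS replicate 2 (0.131). In the same order DML1 (0.133, 0.0516, 0.129 and 0.143) and DML2 (0.174, 0.0860, 0.227 and 0.134) lost theirs.

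Among the remaining lists, 3 of 8 fruit ripening genes fell in NTS, including CNR (-0.59, SE 0.12) and ACO1 (-0.89, SE 0.18), and 1 rose and 3 fell adjusted over the list alone. The small heat shock gene HSP21 rose by 1.91 (SE 0.39), 1 of 7 heat shock genes, with 2 adjusted over the list alone. The dicer gene DCL2b rose by 0.50 (SE 0.12), 1 of 8 RNA silencing genes, and 1 adjusted over the list alone. Over all tested genes 14.9% were called in NTS vs WT, so counts such as 1 of 7 or 1 of 8 do not set a list apart. CPT1, of terpene synthesis in glandular trichomes, rose from 0.346 ± 0.242 to 2.23 ± 0.934 CPM, 1 of 2 trichome genes that rose among 3 tested, with 2 adjusted over the list alone. Of 8 circadian clock genes, none with a checked name, 1 rose and 1 fell, over all genes and adjusted over the list alone, and 0 were called by DESeq2. No floral gene of 5, RNA-directed DNA methylation gene of 5 or CETS gene of 3 was called by edgeR or by DESeq2, with 1, 2 and 1 at an unadjusted p under 0.05. The single tocopherol epiallele gene rose only adjusted over the list alone (log2 fold change 0.39), and DESeq2 called it. Median and mean differed in sign for the clock list (0.01 and -0.00), and camera ranked the RNA-directed DNA methylation list downward although both were 0.01 (adjusted p = 0.871). CNR, ACO1, HSP21 and DCL2b lost their calls without each WT and each NTS library, with edgeR adjusted p from 0.0581 (ACO1) to 0.237 (DCL2b). CPT1 lost its call without WT replicate 1 (0.129) and NTS replicate 1 and 2 (0.108 and 0.154), and its log2 fold change of 2.66 was 3.65 without WT replicate 2.

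In NTS 1914 genes rose and 1022 fell, of 19750 tested. Of genes without a checked name, Solyc11g027887.3 had no WT count and 1.62 ± 0.417 CPM in NTS, while Solyc07g066330.3 fell from 23.1 ± 1.59 to 1.46 ± 0.809 CPM and Solyc11g066800.2 from 9.99 ± 3.11 to 0.719 ± 0.0451 CPM. The count of changed genes was 71 without NTS replicate 1, 320 without NTS replicate 2, 319 without WT replicate 1 and 1712 without WT replicate 2. Of the 30 calls named by the rule for this comparison, 22, 18, 17 and 12 lost their call in the same order. CMT3 had an edgeR adjusted p of 0.0915, 0.0549 and 0.0608 in the first 3 of these fits, while CHI9, CAB1B and PIIF stayed under 0.05 in all 4. Solyc11g027887.3 lost its call without NTS replicate 1 and 2 (0.0793 and 0.0611) and Solyc11g066800.2 without NTS replicate 1 (0.0768). Solyc07g066330.3 had a log2 fold change of -3.94, and of -4.70 without NTS replicate 2.

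**Figure D2:**
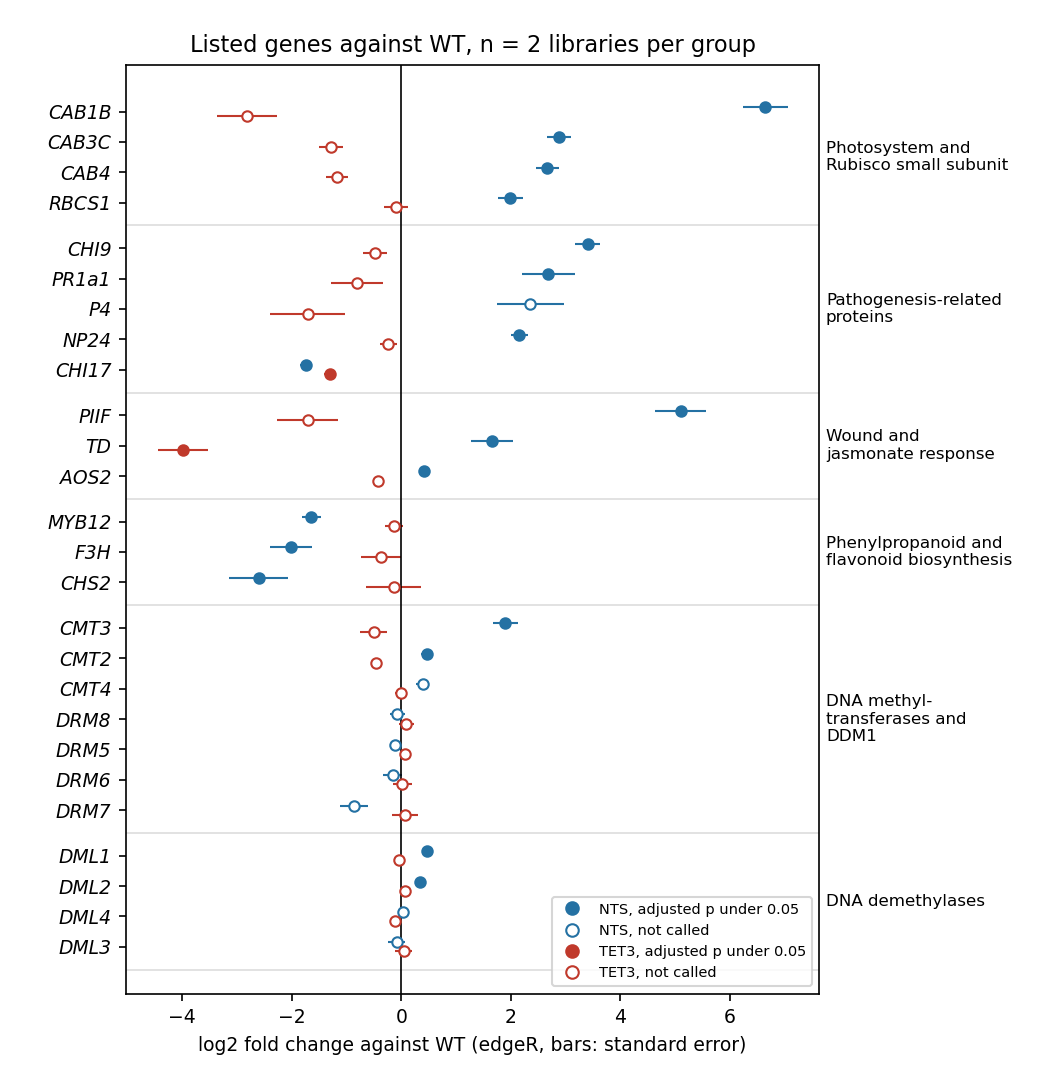
Log2 fold changes against WT (x axis, with standard errors) of listed genes (y axis) in NTS (blue) and TET3 (red), by gene list, n = 2 libraries per group. Filled points have an edgeR adjusted p under 0.05. CAB1B lies at 6.65 in NTS and at -2.82 in TET3, and CHI17 is below 0 in both.

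Repeat families in NTS changed in both directions against WT. Of 619 families 24 rose and 10 fell, with a median log2 fold change of -0.09. The family rnd-5_family-237 rose from 25.3 ± 5.94 CPM in WT to 195 ± 8.68 in NTS (log2 fold change 2.95, SE 0.19, edgeR adjusted p = 0.000189). It is a Caulimovirus family that its class name places under LTR, and it counts among the LTR families here. The Gypsy family rnd-6_family-2701 rose by 2.89 (SE 0.37), or by 3.82 and 2.29 without WT replicate 1 and 2. The family rnd-5_family-2250 fell, with -3.64 (SE 0.19). Of the 24 families that rose 21 were LTR families, 19 of them Gypsy, against 3 of 353 families of other classes (Fisher's exact test, odds ratio 9.97, adjusted p = 4.00e-05). The LTR class as a whole showed no such rise. Its median log2 fold change was -0.02, beside -0.13 for the other families. LTR families summed to 6029 ± 158 CPM in NTS and 5806 ± 488 in WT (SD, n = 2). Scaling on repeat counts alone gave 43 that rose and 26 that fell, with 35 LTR families among the 43. The number of calls was 13 without WT replicate 2, 21 without WT replicate 1, 20 without NTS replicate 1 and 15 without NTS replicate 2.

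Set directly against the NTS libraries, the TET3 libraries were lower in all 7 photosystem and Rubisco small subunit genes, also adjusted over the list alone. CAB1B stood at 0.425 ± 0.00436 CPM in TET3 and 304 ± 139 in NTS, a log2 fold change of -9.46 (SE 0.49, edgeR adjusted p = 0.00109). PIIF (-6.81, SE 0.52), TD (-5.64, SE 0.48) and AOS2 (-0.85, SE 0.07) were lower in TET3 as well, among 4 of 13 wound genes. Of 8 pathogenesis-related genes 4 were lower, such as CHI9 (-3.89, SE 0.23) and the PR protein gene P4 (-4.07, SE 0.68), and CHI17 was higher (0.44, SE 0.11). Of 10 flavonoid genes 3 were higher, such as CHS2 (2.46, SE 0.54) and MYB12 (1.51, SE 0.18). CHS2 lost this call without TET3 replicate 1 (edgeR adjusted p of 0.0838) and NTS replicate 2 (0.0754), and stood at 3.32 without NTS replicate 1. P4 lost its call without TET3 replicate 1 (edgeR adjusted p of 0.0596), NTS replicate 1 (0.0594) and NTS replicate 2 (0.0578). For these 3 lists the counts adjusted over the list alone were the same. Camera called all 4 lists (adjusted p = 1.99e-18 for photosystem, 0.0288 for wound, 0.000484 for pathogenesis-related and 0.0277 for flavonoid). The same lists had adjusted p = 0.290, 0.517, 0.404 and 0.517 with an estimated correlation. Fry called the photosystem (adjusted p = 0.0188) and pathogenesis-related lists (0.0331) but not the wound (0.0820) or flavonoid list (0.103). Fry also called the methyltransferase (adjusted p = 0.0248), fruit ripening (0.0331) and heat shock lists (0.0419), which camera did not. Camera no longer called the wound and flavonoid lists without TET3 replicate 1 (adjusted p = 0.673 and 0.207) or NTS replicate 2 (adjusted p = 0.0785 for both), nor the wound list without WT replicate 1 or 2 (adjusted p = 0.0995 and 0.0997).

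CMT3 was lower in TET3 than in NTS (-2.40, SE 0.23, edgeR adjusted p = 0.00272), as were CMT2 (-0.92, SE 0.10) and CMT4 (-0.40, SE 0.11). DRM7, a domains-rearranged methyltransferase, was higher (0.93, SE 0.25). In all 5 of 10 genes of that list were lower and 1 higher, with the same counts adjusted over the list alone. DML1 (-0.52, SE 0.09) and DML2 (-0.29, SE 0.08) were lower among 4 demethylase genes, also adjusted over the list alone. DCL3, which makes small RNAs for RNA-directed DNA methylation, was higher (0.59, SE 0.10), 1 of 5, with 2 adjusted over the list alone. ACO1 (1.32, SE 0.18) and CNR (0.67, SE 0.12) were among 3 of 8 ripening genes that were higher, while ACS2 (-1.13, SE 0.33) was lower, and 4 were higher and 1 lower adjusted over the list alone. FUL1 was the 1 floral gene of 5 that was higher (0.94, SE 0.24), also adjusted over the list alone. Over all 19750 tested genes 29.9% were called between TET3 and NTS, so list counts near or under that share do not set a list apart. HSP21 (-1.76, SE 0.37), HSP20.0 and HSP17.8 (Solyc06g076560.2, a name not certain among its neighbours) were lower among 7 heat shock genes. CPT1 was 1 of 2 lower genes among 3 of glandular trichomes. The counts of both lists were the same adjusted over the list alone. Of 8 clock genes 1 was higher and 1 lower on both adjustments. No CETS gene of 3, RNA silencing gene of 8 or tocopherol gene was called by edgeR or DESeq2, or adjusted over the list alone, and 2 of these 12 genes had an unadjusted p under 0.05. CMT4, DRM7, DML1, DML2, DCL3, CNR, ACS2, FUL1, HSP21, HSP17.8 and CPT1 lost their calls without NTS replicate 1 and without NTS replicate 2, with edgeR adjusted p from 0.0563 (DCL3) to 0.220 (ACS2), and ACO1 and HSP20.0 without NTS replicate 1 (0.0580 and 0.122). Without TET3 replicate 1 and 2 CMT4 (0.0907 in the latter case), DML2 (0.0574 and 0.133), FUL1 (0.0794 and 0.0975), HSP17.8 (0.105 and 0.108) and CPT1 (0.105 and 0.0627) lost theirs. ACS2 (0.153) and HSP20.0 (0.0531) did so without TET3 replicate 1, and DRM7 (0.103) and HSP21 (0.0599) without TET3 replicate 2. Without WT replicate 1 and 2, DML2 (0.0592 and 0.0586) and ACS2 (0.0600 and 0.0590) were not called either.

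Between TET3 and NTS 2439 genes were higher and 3458 lower in TET3, of 19750 tested. Solyc07g066330.3, at 66.9 ± 15.7 CPM in TET3 and 1.46 ± 0.809 in NTS, and Solyc10g009150.3, with no count in TET3 and 24.4 ± 5.62 CPM in NTS, were among the largest differences. The former had a log2 fold change of 5.47, and of 6.24 without NTS replicate 2. Without NTS replicate 1 the count was 1108 and without NTS replicate 2 it was 2049, and 16 and 15 of the 34 gene calls named for this comparison were then lost, beside 11 and 7 without TET3 replicate 1 and 2 and 2 without either WT library. Of 619 repeat families 197 were higher and 3 lower in TET3, with a median log2 fold change of 0.37. The share of LTR families that were higher did not pass the test with edgeR calls, with 84 of 266 higher against 113 of 353 others (Fisher's exact test, odds ratio 0.980, adjusted p = 0.931). With DESeq2 calls LTR families were over-represented, with 77 of 215 against 70 of 298 others (Fisher's exact test, odds ratio 1.82, unadjusted p = 0.00294). rnd-5_family-1060 was higher in TET3 (1.48, SE 0.16), and rnd-5_family-237 lower (-1.86, SE 0.18). Scaling on repeat counts alone moved the median log2 fold change to 0.00 and gave 25 higher and 23 lower. The number of called families was 10 without NTS replicate 1, 37 without NTS replicate 2 and 94 without TET3 replicate 2.

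Changes found both with the transgene and in the sibling without it bear on whether an altered state persisted. CHI17 fell in both groups against WT. Solyc02g150124.1 had 0.0417 ± 0.00276 CPM in WT, 14.2 ± 3.40 in TET3 and 12.2 ± 0.223 in NTS, and Solyc01g058705.1 stood at 0, 6.25 and 6.97 CPM. In all 31 genes rose in both and 29 fell in both, against 13.3 same-direction genes from independent lists. In 60 simulations of unchanged groups with shared WT libraries the mean was 0.183 (highest 2). No gene was changed there, so few passed the adjusted threshold and a shared count near 0 was fixed in advance. That count is no measure of the excess. Another 47 genes were called in opposite directions, where independent lists give 16.3, and 42 of them were lower in TET3 and higher in NTS, as TD was. Of the 60 same-direction genes 24 also differed between TET3 and NTS. The correlation of log2 fold changes over all genes was -0.01 (0.51 in the simulations), and their covariance was -0.00471 beside a simulated 0.0440. The WT group of 2 libraries could not be split, so how much of the excess over independent lists comes from the shared controls could not be told. The count of 60 was 0 without WT replicate 1 and 0 without WT replicate 2, 2 without NTS replicate 1 or 2, 137 and 155 without TET3 replicate 1 and 2, and 154 with DESeq2.

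Among repeats, Gypsy families carried most of the overlap. Of 21 families called the same way in both groups 18 rose, and of these 17 were LTR families and 15 Gypsy. They included rnd-6_family-2701, rnd-6_family-432, rnd-5_family-1961, rnd-5_family-585 and rnd-3_family-50. The family rnd-3_family-50, for example, stood at 6.23 ± 0.825 CPM in WT, 25.4 ± 3.36 in TET3 and 22.6 ± 0.736 in NTS. The 3 families that fell in both were rnd-5_family-2250, rnd-5_family-879 and rnd-4_family-567. Independent lists give 4.56 same-direction families, and 1 family was called in opposite directions. The simulations gave a mean of 0.05 (highest 1), a value near 0 that was fixed in advance as for genes. Log2 fold changes correlated at 0.68 over families (0.51 in simulations), with a covariance of 0.167 beside a simulated 0.0301. Yet only 44.7% of families had the same sign in both comparisons, beside 66.8% in the simulations. Families above 0 made up 88.7% in TET3 vs WT and 36.0% in NTS vs WT, so families as a whole did not move together. Of the 21 families 5 also differed between TET3 and NTS. Against WT, rnd-5_family-879 lost its NTS call without each WT and each NTS library (edgeR adjusted p from 0.0906 to 0.188) and its TET3 call without each library but TET3 replicate 1 (0.0605 to 0.140). The TET3 call of rnd-6_family-432 was lost without WT replicate 2 (0.0564). With scaling on repeat counts alone 27 families were shared, 18 of them the same families, and without WT replicate 2 there were 8 and without NTS replicate 2 there were 11.

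**Figure D3:**
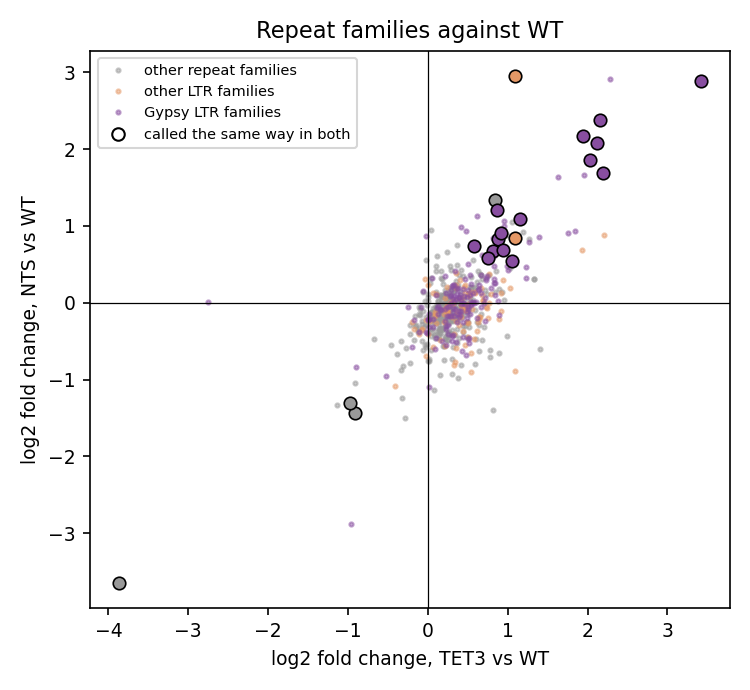
Log2 fold change of each repeat family in NTS vs WT (y axis) against TET3 vs WT (x axis), from 2 libraries per group. Colours give the class, and outlined points are the 21 families called the same way in both comparisons. Of the 18 outlined families above 0 on both axes 15 are Gypsy.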

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

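Reads of the transgene were seen in libraries of plants described as lacking it, above the level of the WT libraries. NTS replicate 1 held 13.7 CPM of TET3c (exact 95% interval 12.2 to 15.4) and NTS replicate 2 held 1.96 CPM (1.47 to 2.56), while the WT libraries held 0 and 0.166 CPM, the latter with an interval up to 0.426. These levels are 0.137% and 0.0196% of the TET3 mean, and no explanation was tested. Of the tests below, those of scaling, time of day, depth, leaf state and shared controls were chosen only after the result was seen.

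The share of repeat counts was higher in TET3 than in WT in each library, by a ratio of 1.19. Reads spread over the genome, such as genomic DNA, were predicted to raise genes that are hardly expressed as much. The 5746 genes with a mean under 0.5 CPM showed no such rise, with a TET3 over WT ratio of 0.998 (0.976 to 1.02 over pairs of libraries). Such reads add counts by sequence length, however, and lengths were not available for want of coordinates. The rise they would cause in these genes is thus unknown, and such reads stay open. Of the difference 88.5% remained without the 10 largest families. The shares are unscaled, so their gap of 0.203 percentage points between the lowest TET3 and the highest WT library restates the pattern and tests nothing about scaling. Reads of host genes of repeats stay open for want of coordinates, as does loss of DNA methylation at LTR elements through the transgene, a hypothesis that these data did not test.

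The NTS libraries stood apart from WT and TET3. The 8 tested genes of the clock list had a median absolute log2 change of 0.10 in NTS vs WT, at percentile 4.06 of 10000 expression-matched lists, whose median was 0.23, but none of their names could be checked, so a shift of sampling time stays open. Depth differed in no 1 direction, since 1 of the NTS libraries was larger than both WT libraries and the other smaller. The log2 ratio of WT replicate 2 over WT replicate 1 correlated with NTS over TET3, which uses no WT library, with r = 0.34 and a slope of 15.5% across 19750 genes, which are not independent replicates, and had the same sign for 73.0% of the 5897 genes called between TET3 and NTS. Part of the difference may follow a state of the leaf, such as its stage, that also varies within a genotype, though CAB1B and TD ran the other way, with TD at 61.9 CPM in WT replicate 1 and 33.3 in WT replicate 2, and descent from a transgenic parent remains open and untested.

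Of the 60 genes called the same way in TET3 and NTS, 6 of the 59 that could be placed lay within 10 gene positions of another, where permutation draws gave 2.39 on average and 6 at their 95th percentile (permutation p = 0.106). This argues against tight blocks of neighbouring genes as the source of most of them. Longer segments were not tested and stay open. Chromosome 7 held 11 of the genes where 4.50 were expected from its tested genes, the largest excess of any chromosome and picked after the counts were seen. Chromosome 6 held 1 where 5.24 were expected. Simulated unchanged groups shared at most 2 calls, but with no gene changed hardly any could pass the threshold, so this decides nothing. With 2 WT libraries the controls cannot be split, so chance in the shared controls and changes common to both groups cannot be told apart. Changes that outlast the transgene remain a hypothesis.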

How the results depend on the processing

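Of 101 calls of named genes and families, which leave out TD in NTS vs WT and TET3 vs NTS, all 101 kept their call with RLE size factors. The call was kept by 95 without the low-count filter, 91 of 98 with DESeq2 and 89 with only the groups compared, and 0 reversed under any alternative. Between 47 and 87 kept it without 1 library, where the lone sample is assumed to vary like the other groups. The cause of the moves below was not tested, except that fewer libraries leave fewer degrees of freedom.

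For TET3 vs WT genes (199) the count was 349 without the filter, 1081 with DESeq2, 5 with only the 2 groups and 0 to 651 without 1 library. NTS vs WT genes (2936) gave 71 to 3902 and TET3 vs NTS genes (5897) 1108 to 5291 without 1 library. A minimum log2 change of 1 left 136, 1180 and 2377 genes. Shared genes (60) numbered 154 with DESeq2, 28 at that minimum and 0 to 155 without 1 library.

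For repeat families, TET3 vs WT (121) gave 63 with only the 2 groups, 38 with TMM on repeats alone, 23 at a log2 change of 1 and 12 to 105 without 1 library. NTS vs WT (34) gave 69 with TMM on repeats alone, 64 with rows as deposited (chosen after seeing the data), 15 at the minimum change and 13 to 41 without 1 library. TET3 vs NTS (200) gave 48, 27 at the minimum change and 10 to 193. Shared families (21) gave 36 with rows as deposited, 9 at the minimum change and 8 to 23. The repeat share of TET3 exceeded that of NTS by 0.421 percentage points, and by 0.352 without the 10 largest families.

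The replicate block gave 32, 1910 and 4884 genes in TET3 vs WT, NTS vs WT and TET3 vs NTS, 55, 33 and 114 families, and 12 shared genes. The samples share only a number, since deviations of same-numbered libraries correlated at -0.14 (WT and TET3), -0.01 (WT and NTS) and 0.17 (TET3 and NTS).

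By fry for a common direction the smallest adjusted p of a gene list in TET3 vs WT was 0.306. In NTS vs WT fry called the photosystem list (adjusted p = 0.0270) but neither the pathogenesis-related (0.0680) nor the flavonoid list (0.0791). Gene lists called by camera numbered 3, 3 and 4, and 0 with an estimated correlation. Without 1 library they ranged over 0 to 2, 3 to 4 and 2 to 6. LTR families were over-represented among rises in TET3 and in NTS in all 12 alternative fits, with a lowest odds ratio of 3.41 in TET3 and 6.58 in NTS. In NTS this concerns the called families only, since the median LTR log2 fold change was -0.02 in the main fit. The planned tests of repeats near or overlapping genes were not run, for want of coordinates. The 15149 features under the filter had too few counts to be tested, and whether depth or lack of expression was the reason was not tested.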

Other observations

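The 5 Caulimovirus families, relics of plant DNA viruses within the genome, summed to 92.5 ± 15.5 CPM in WT, 137 ± 15.4 in TET3 and 258 ± 11.2 in NTS (SD, n = 2). A single family, rnd-5_family-237, accounted for the high sum in NTS, and the other 4 summed to 67.3 ± 9.61 CPM in WT, 83.2 ± 4.88 in TET3 and 62.7 ± 2.52 in NTS. Only that 1 family of the 5 rose in NTS vs WT by edgeR at an adjusted p under 0.05, and as a set they were not called by camera (adjusted p = 0.259). The DNA transposon group given only as DNA had 0 of 33 families that rose and 4 that fell in NTS, and 2 that rose and 2 that fell in TET3. Genes with a mean under 0.5 CPM summed to 766 and 714 CPM in the NTS libraries, 615 and 629 in TET3 and 616 and 630 in WT.

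The comparison in this paragraph was fixed before its result, but the reading of a tie, and the limit of 3 counts per library in place of the group sum, were settled after the counts were seen. If TET3 and NTS shared switches, more genes would be silent in WT alone or expressed in WT alone than for another group. Silence was set at up to 3 counts in each library and expression at 1 CPM or more in each. With both kinds counted, 5 genes set WT apart from both other groups, 5 set NTS apart and 1 set TET3 apart. In this total there was no excess for WT over NTS. Read strictly as first written, a tie counts against shared switches, and counts this small do not separate the groups. The 2 kinds differed, however. All 5 genes that set WT apart were silent in WT, while 0 genes were silent in TET3 alone and 0 in NTS alone. All 5 that set NTS apart were expressed in NTS alone, beside 1 in TET3 alone and 0 in WT alone. The tie thus holds for the total and not for either kind.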
